A study of Arabidopsis thaliana with 14 samples.

How the data were processed

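Binding of FLM, a MADS-box transcription factor that regulates flowering time, was measured by chromatin immunoprecipitation with sequencing (ChIP-seq) in Arabidopsis thaliana Columbia-0 seedlings. FLM carried a GFP tag and was precipitated with an antibody against GFP, and plants with untagged FLM were the controls, per the labels. The 14 libraries fall into 3 constructs. gFLM had 3 GFP and 3 control libraries from seedlings grown for 15 days at 16 °C. The splice variants iFLMbeta and iFLMdelta had 2 GFP and 2 control libraries each, from seedlings grown for 10 days at 23 °C. All material was collected at zeitgeber time 8 h under long days. What the prefixes g and i stand for is not stated in the labels. gFLM against either variant therefore mixes construct with age and temperature, and iFLMbeta against iFLMdelta does not. The labels do not say whether replicates came from separate plant pools. The p-values of edgeR and DESeq2 therefore measure only the spread between these libraries, which may be technical. Those of Fisher's exact test and of random placements take genes or regions as units and hold no spread between libraries.

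Libraries were amplified by PCR and sequenced on a Genome Analyzer II, per the labels' protocols, and the genome build was TAIR10, per the submitters' processing notes. The aligner, the peak caller and the handling of duplicate reads are not given in the sources used here. The authors deposited 1 table of regions per construct. Each row holds the region's position and size, the raw read count in each GFP and each control library, a Benjamini-Hochberg q-value per replicate, the log2 of the rank product of these q-values and the rank of that product, per the file headers. It also holds the genes at the region's centre and the nearest gene on each side. The deposited read counts are whole numbers with no normalization. The tables hold no total of mapped reads per library, so the sums over deposited regions given here are not sequencing depths. They ranged from 17293 to 437712 reads in gFLM, where replicate 2 was the lowest of both kinds. The ranges were 52819 to 194811 in iFLMbeta and 71083 to 211113 in iFLMdelta. Reads have no molecular identifiers. The intervals given below take regions as units and hold no spread between libraries. For iFLMbeta and iFLMdelta the columns name a construct and a column number but no single library. edgeR used them as unnumbered replicates of their group, and 0 columns of per-sample values were left without a sample or group.

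The threshold needs a statement of its own. The plan written before the data were examined called for a combined FDR or q of 0.05, or for every region as deposited where no such column existed. The tables hold q-values per replicate and no combined one. A region was taken to pass where q was 0.05 or less in every replicate of its construct, and this reading was chosen after the columns had been seen. The counts of all deposited regions are given beside it. The deposited lists contain many regions with a low q in 1 replicate only.

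Within each construct, GFP libraries were compared with control libraries by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment. Because regions were called on the same libraries, this test is circular and describes how firmly the counts separate GFP from control. Ratios per replicate are log2 of (GFP reads + 1) over (control reads + 1), scaled by the reads in all deposited regions of both libraries. Each GFP column was set against the control column of the same number. For iFLMbeta and iFLMdelta this pairing rests on column numbers alone, and so do the SDs, the values per replicate and the counts of ratios above 0 in both replicates. The means over replicates do not depend on it. With the control columns crossed, the median SD over passing regions was 0.54 in place of 0.38 in iFLMbeta and 0.62 in place of 0.25 in iFLMdelta. Since deposited regions were selected for GFP reads, this scaling lowers the ratios, and a region can pass by the authors' q-value with a ratio near 0. Enrichment was compared between constructs at regions deposited for both by an edgeR interaction term, adjusted over regions passing in either construct. Regions that passed in 1 construct were selected on one side of that difference, which favours finding it. The interaction fits that involve gFLM were added after seeing the data.

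Overlap meant 1 bp or more. It was compared with 100 random placements of the second list on the same chromosomes, whose extent was taken from the outermost deposited regions, and the smallest p these can give is 0.0099. A second comparison, with regions drawn at random from the second construct's deposited list, was added after seeing the data. A gene was assigned a region whose centre lay between 3 kb upstream of its start and 1 kb past its end, from the distances and strands in the tables. Some rows are cut short after the gene annotation. Missing strands and distances were filled from other rows of the same tables, which left 288 gFLM, 62 iFLMbeta and 46 iFLMdelta regions without a strand for the right neighbour. The 6 gene lists were fixed before the data were examined: flowering time, floral organ identity, circadian clock, gibberellin, light and temperature, and a control list of highly transcribed genes. They were tested by Fisher's exact test, two-sided, against 37899 nuclear genes of a RefSeq gene table (assembly TAIR10.1), which was used for names and this background only. It held 235 of the 240 genes assigned in gFLM, 302 of 308 in iFLMbeta and 63 of 64 in iFLMdelta. Adjustment was over 18 tests. The plan called for random placements as the background for the position of regions. That needs an annotation not used here, so passing regions were set against the other deposited regions of the same table. CArG boxes, the binding sites of MADS-domain proteins, were not analysed here because no genome sequence was used.

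Named genes followed a rule fixed before the data were examined: the genes nearest to the 10 best ranked regions of each construct, every listed gene with a passing region, the 5 best ranked passing regions of each variant not found in the other, and FLM, SOC1, SVP, FT, SEP3, AP3, PI, SHP2, ATC, TEM2 and RVE2 in any case. Genes named outside this rule are said to be so. Alternatives covered the threshold, normalization (TMM, DESeq2 size factors, total reads), DESeq2 1.42.0 in place of edgeR, the filter on low counts, each library left out, windows and overlap definitions. Same-numbered gFLM GFP and control libraries deviated together from their group means, with correlations across regions of 0.542, 0.252 and 0.137. Differently numbered ones correlated at -0.398 to 0.094. The replicate numbers were therefore taken to pair the libraries, as read from the data and not from the labels. For replicate 3 this rests on little, since its GFP library correlated at 0.094 with the control library of replicate 2. The edgeR test was tested on simulated counts drawn from the real means and library sizes. The spread between simulated replicates was fixed and not estimated from these libraries, and the changed regions left out those of lowest mean counts. Where the real spread is wider, fewer regions would be recovered than given here. At a 4-fold change it recovered 90.0% of 50 changed regions in gFLM (19893 regions simulated), 50.0% in iFLMbeta (13791) and 76.0% in iFLMdelta (10006). At a 2-fold change it recovered 4.0%, 0.0% and 2.0%. Among real gFLM regions, edgeR fitted log2 changes of 2.08 at SVP, 2.20 at SPT and 2.61 at DMR6. It called none of these 3 (adjusted p = 0.297, 0.259 and 0.131), and it called CBF1 at 2.93 (0.0194). The simulated recovery at 4-fold is therefore likely too high for the gFLM libraries. The interaction test recovered 35.9% of the regions changed 4-fold between iFLMbeta and iFLMdelta (733 regions simulated). Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9.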

Results

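The series profiles where GFP-tagged FLM sits on chromatin in whole seedlings, for gFLM and for the splice variants FLMbeta and FLMdelta. Each GFP group was read against untagged controls of its own: 3 against 3 libraries for gFLM and 2 against 2 for each variant. Coordinates are those of build TAIR10. Enrichment is given as the mean log2 ratio of GFP to control reads ± SD over replicates.

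gFLM was found at regions near regulators of flowering and floral development. SEP3, a MADS-box gene of floral organ identity, had the third best ranked region of the list (chromosome 1, 8598618 to 8599018). It is intergenic, 2712 bp upstream of SEP3 and 1647 bp upstream of AT1G24265, with a log2 ratio of 3.77 ± 0.58 (SD, n = 3). ATC, a relative of the flowering repressor TFL1, had a region 1552 bp upstream (chromosome 2, 11771531 to 11771867) at 3.34 ± 0.92 (SD, n = 3). SOC1, an activator of flowering, had one 114 bp upstream of its start (chromosome 2, 18810997 to 18811327) at 2.93 ± 0.43 (SD, n = 3). In edgeR's quasi-likelihood test the adjusted p was 1.32e-04 for SEP3, 0.0015 for ATC and 0.0248 for SOC1, and the ratio was above 0 in 3 of 3 replicates at each. Without the filter on low counts all 3 calls ended (0.461, 0.613 and 1). The SEP3 call also ended without the GFP library of replicate 2 (0.0946), and that of ATC without the GFP library of replicate 1 (0.0886) or 2 (0.147). The SOC1 call ended with scaling by total reads (0.0532), without the GFP library of replicate 1 (0.416), 2 (0.565) or 3 (0.21), without the control library of replicate 3 (0.346) and without both libraries of replicate 2 (0.504). Over the alternatives the adjusted p ran from 1.95e-12 to 0.461 for SEP3, from 1.24e-10 to 0.613 for ATC and from 1.88e-05 to 1 for SOC1.

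In all, 159 gFLM regions had q of 0.05 or less in every replicate, out of 19893 deposited. If the replicates were independent, 1.8 would be expected. The median log2 ratio of the 159 was 1.68, and all 159 had ratios above 0 in every replicate. The 10 best ranked lay at AT2G20440, AT3G15470, AT1G24265 (the SEP3 region), AT2G30600, AT5G41071, AT1G22460, ABCG20, SPA2, AT1G44010 and LEJ2. The first of these (chromosome 2, 8813484 to 8813859) lies between AT2G20440 and AT2G20450 with 4.31 ± 0.09 (SD, n = 3), from 876, 245 and 268 GFP reads against 18, 2 and 15 control reads. The AT3G15470 region is in the 3' UTR (chromosome 3, 5216238 to 5216578) at 3.36 ± 0.25 (SD, n = 3). The SPA2 region is in an intron (chromosome 4, 6771765 to 6772158) at 4.04 ± 1.11 (SD, n = 3). SPA2 encodes a repressor of light signalling. The region at LEJ2 is intergenic, 2484 bp upstream of LEJ2 and 4786 bp from AP2. By edgeR, 30 of 5230 tested regions were higher in GFP and 0 lower. With the replicate numbers as a block, which pairs the libraries, 115 were higher and 1 lower. Without the GFP library of replicate 2 the count was 6, without that of replicate 1 it was 9, and without the GFP or the control library of replicate 3 it was 14.

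iFLMbeta occupied many of the same places. It had 202 passing regions of 13791 deposited (98.6 expected from independent replicates), with a median log2 ratio of 1.01. Ratios were above 0 in both replicates at 197 of them, and at 174 with the control columns crossed. Its best ranked region was that in the 3' UTR of AT3G15470 (chromosome 3, 5216243 to 5216547) at 3.21 ± 0.23 (SD, n = 2), followed by the SEP3 region (chromosome 1, 8598646 to 8599006) at 3.42 ± 0.84 (SD, n = 2). Next came AT2G30600, AT2G20440, AT1G22460, AT5G41071, ATC, SPA2, ABCG20 and AT3G03460. ATC stood at 3.40 ± 0.78 (SD, n = 2) and SOC1 at 2.26 ± 1.35 (SD, n = 2). With the control columns crossed the SD was 0.07 for SEP3, 0.58 for ATC and 0.18 for SOC1. At other listed genes named below, crossing raised it for SHP2 (0.26 to 1.21), PI (0.33 to 1.14) and RVE2 (0.59 to 1.30). It also rose for SVP (0.31 to 0.80), TEM2 (0.17 to 0.47) and PIF3 (0.23 to 0.69). It fell for SMZ (1.36 to 0.27), AP3 (1.59 to 0.59) and CBF1 (1.29 to 0.59). Adjusted p by edgeR was 3.75e-15 for SEP3, 5.91e-09 for ATC and 0.0153 for SOC1. The SEP3 call was kept under every alternative run (5.75e-12 to 0.0359). The ATC call ended without the first control library (0.0976) or the second (0.0574), with a range of 1.8e-07 to 0.0976. The SOC1 call ended with DESeq2 (0.0541), without the filter on low counts (0.115), with the column numbers as a block (0.196), and without the second GFP library (1), the first control library (0.775) or the second (1), with a range of 0.014 to 1. edgeR called 25 of 7337 tested regions higher and 0 lower. That count was 5 without the second GFP library, 3 without the first control library and 5 without the second.

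iFLMdelta gave few regions that both replicates shared. Of 10006 deposited regions 41 passed, below the 84.2 expected from independent replicates. The median log2 ratio of the 41 was 1.03, and at q of 0.01 or less in both replicates 0 were left. The best ranked region lies in a coding exon of AT2G39300 (chromosome 2, 16410770 to 16410981) at 1.61 ± 0.05 (SD, n = 2), from 36 and 17 GFP reads against 4 and 3 control reads. Others of the best 10 that passed were a coding exon of AT1G56040 and introns of DEG7 and AT1G61240. The remaining 6, in or near PIF4, AT4G14390, AT5G55896, AT1G50350, AT1G35570 and ACD6, missed the threshold in 1 replicate. At PIF4, a regulator of growth in warmth, the log2 ratio was 1.13 in replicate 1 and -0.47 in replicate 2 (chromosome 2, 17887318 to 17887793, coding exon). edgeR called 0 of 4607 tested regions, with 6 higher at an unadjusted p under 0.05, and DESeq2 called 0 with 1.

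**Figure D1:**
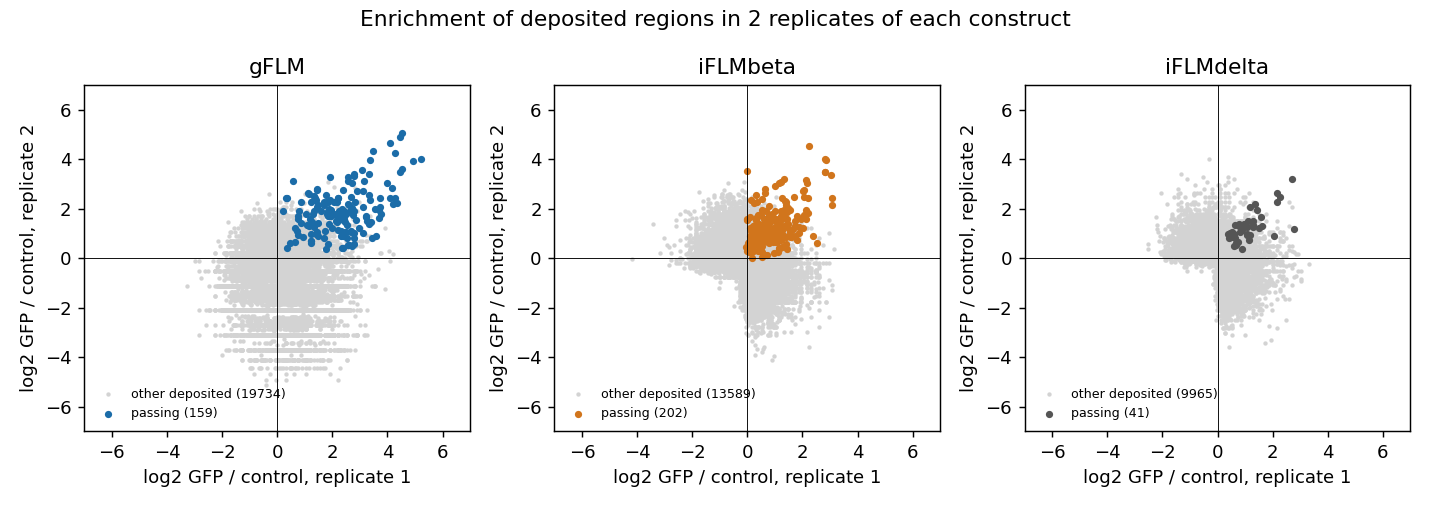
Each point is a deposited region, with the log2 ratio of GFP to control reads (scaled by reads in deposited regions) in replicate 1 on the x axis and in replicate 2 on the y axis, for gFLM, iFLMbeta and iFLMdelta. Coloured points pass q of 0.05 in every replicate (159, 202 and 41), and grey points are the other deposited regions, most of which are high in 1 replicate at most in the variants.

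Across all deposited regions the mean Spearman correlation of replicate ratios, across regions that are not independent replicates, was -0.11 in gFLM, -0.44 in iFLMbeta and -0.49 in iFLMdelta. The deposited lists hold many regions with a low q in 1 replicate only, and such a selection favours values below 0. The GFP read counts themselves correlated between replicates at 0.31 to 0.64 in gFLM, 0.35 in iFLMbeta and 0.32 in iFLMdelta. Ratios above 0 in every replicate were found at 5.0% of gFLM regions, over 3 replicates, and at 12.9% and 17.9% of iFLMbeta and iFLMdelta regions, over 2. These shares cannot be set against a chance level, because the scaling lowers the ratios and the lists are selected. Among passing regions the lowest correlation between 2 replicates was 0.31 in gFLM, 0.41 in iFLMbeta and 0.62 in iFLMdelta, but these were selected for low q in each replicate. With the control columns crossed the last 2 were 0.12 and -0.16.

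The question of whether the constructs share target regions was addressed by overlap. Of the 202 iFLMbeta regions, 109 overlapped a passing gFLM region (54.0%, 95% Wilson interval 47.1 to 60.7), and these were 68.6% of the 159 gFLM regions. Random placements of the gFLM list gave 0.16 on average and at most 3 (permutation p = 0.0099, the smallest they can give). Regions drawn from the deposited gFLM list gave 1.54 on average and at most 5. The 20 best ranked regions of either construct all passed in the other. Any deposited gFLM region was overlapped by 185 of the 202, and any deposited iFLMbeta region by 149 of the 159. No passing iFLMdelta region overlapped a passing region of gFLM or iFLMbeta (0 of 41 for each, upper 95% bound 8.6%). Chance gave 0.05 and 0.04, so an overlap of 0 does not differ from random placement. Against all deposited regions, 11 of the 202 iFLMbeta regions had a counterpart in iFLMdelta, where random placements gave 7.76 on average (permutation p = 0.1782).

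**Figure D2:**
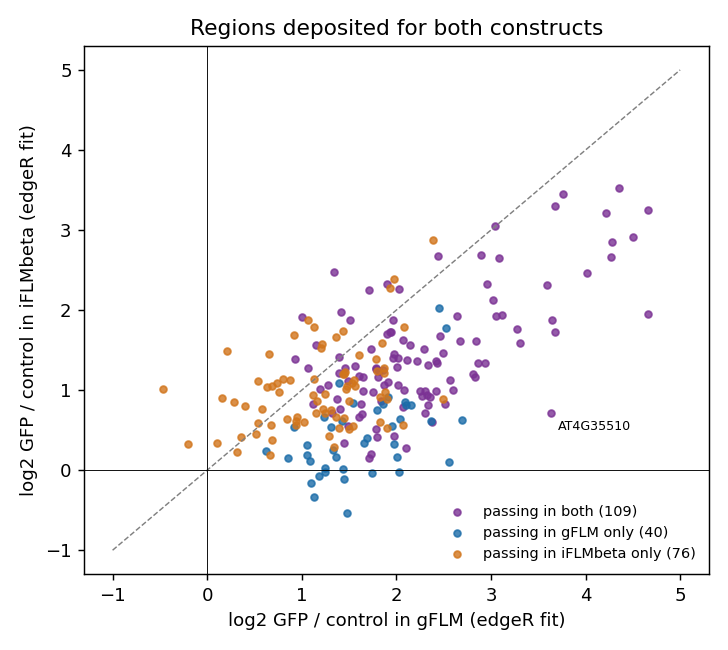
Regions deposited for both gFLM and iFLMbeta that pass in either, with the log2 ratio of GFP to control fitted by edgeR in gFLM (x axis) and in iFLMbeta (y axis); the dashed line marks equal values. Of these, 109 pass in both, 40 in gFLM only and 76 in iFLMbeta only. The labelled region, AT4G35510, is the one whose difference passed the test when adjusted over these regions.

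The splice variants were compared at regions deposited for both. At the 11 of these 733 that passed in iFLMbeta the median log2 ratio was 1.01 in iFLMbeta and -0.15 in iFLMdelta. The median difference was 1.09 (0.53 without the first iFLMdelta GFP library), and 0.29 to 1.92 over the combinations of replicates, with iFLMbeta higher at 11 of 11. These regions were selected for passing in iFLMbeta, which favours that sign. Over all 733 the median difference was -0.09, with iFLMbeta higher at 317, but scaling by the reads in deposited regions sets this median near 0 in each construct, so it does not measure a difference in occupancy. At the 3 regions that passed in iFLMdelta the median difference was -1.12. The edgeR interaction found 0 of the 14 regions to differ, with 2 at an unadjusted p under 0.05. The lowest p values were at AT1G17940 and AT5G38600, each with an adjusted p of 0.239. Without the first iFLMbeta control library 1 region was called. With 2 libraries against 2, exact permutation of a single value cannot go below 0.33, two-sided. The 5 best ranked iFLMbeta regions with no overlap in iFLMdelta were those at AT3G15470, AT1G24265, AT2G30600, AT2G20440 and AT1G22460. The 5 best of iFLMdelta with no overlap in iFLMbeta were at AT2G39300, AT1G56040, DEG7, AT1G61240 and AT1G30680.

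Genes of the flowering list were assigned passing regions more often than other genes. In gFLM 5 of 38 had one, with 0.24 expected (odds ratio 24.8, adjusted p = 6.72e-05, Fisher's exact test), namely ATC, SMZ, SOC1, SVP and TEM2. The same 5 had one in iFLMbeta (odds ratio 19.2, adjusted p = 1.13e-04). ATC, SOC1, SVP and TEM2 were also among the genes to be reported in any case, as were SEP3, AP3 and SHP2 below. How those genes were chosen is not recorded. The p-values of the list tests hold only if the lists owe nothing to earlier reports of FLM binding. SVP encodes a MADS-box repressor of flowering, and SMZ and TEM2 also encode repressors. The SVP region lies in the 5' UTR (chromosome 2, 9579994 to 9580305), at 1.74 ± 0.33 (SD, n = 3) in gFLM and 0.84 ± 0.31 (SD, n = 2) in iFLMbeta. The SMZ region is 2596 bp upstream of SMZ and 2389 bp from TON1A, at 1.59 ± 1.12 (SD, n = 3) and 1.95 ± 1.36 (SD, n = 2). The TEM2 region is 2654 bp upstream of TEM2 and 2118 bp from STN7, at 1.14 ± 1.07 (SD, n = 3) and 1.62 ± 0.17 (SD, n = 2). edgeR over all regions called none of these 3 in either construct. With the replicate numbers as a block, SVP (adjusted p = 0.018) and SMZ (0.0205) were called in gFLM, as they were by DESeq2 (0.00741 and 0.0219), and TEM2 was not (0.191 and 0.233). Over the alternatives the adjusted p in gFLM ran up to 1 at each of the 3. Of the flowering genes with a tested region, edgeR called 2 of 19 in gFLM over all regions and 4 when adjusted over the list alone, and 2 of 25 and 4 in iFLMbeta.

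Among floral organ identity genes, SEP3, AP3 and SHP2 had passing regions in both constructs (3 of 14; adjusted p = 4.56e-04 in gFLM and 6.15e-04 in iFLMbeta, Fisher's exact test). The AP3 region is 120 bp upstream (chromosome 3, 20121080 to 20121502) at 1.40 ± 0.75 (SD, n = 3) in gFLM and 1.43 ± 1.59 (SD, n = 2) in iFLMbeta. The SHP2 region is 360 bp upstream (chromosome 2, 17819732 to 17820057) at 1.48 ± 0.88 (SD, n = 3) and 2.01 ± 0.26 (SD, n = 2). A region 1573 bp past the end of PI passed in both constructs, at 1.68 ± 0.92 (SD, n = 3) in gFLM and 1.43 ± 0.33 (SD, n = 2) in iFLMbeta. It is outside the assignment window and 570 bp upstream of DIN10. Its adjusted p in gFLM was 0.32 by edgeR, 0.0389 with the replicate block and 0.0153 by DESeq2, and up to 1 over the alternatives. edgeR over all regions called SEP3 alone of this list in each construct, of 6 tested genes in gFLM and 10 in iFLMbeta. Adjusted over the list alone the counts were 1 and 2.

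Of the light and temperature genes, CBF1 and PIF3 had passing regions in both constructs and CBF2 in gFLM (3 of 15, adjusted p = 4.56e-04; 2 of 15 in iFLMbeta, adjusted p = 0.019; Fisher's exact test). CBF1 and CBF2 encode activators of the cold response. The CBF1 region is 932 bp upstream of CBF1 and 913 bp from RS40 (chromosome 4, 13023431 to 13023884), at 2.69 ± 0.52 (SD, n = 3) in gFLM and 1.46 ± 1.29 (SD, n = 2) in iFLMbeta, with an adjusted p by edgeR of 0.0194 and 0.708. The difference between the constructs was not called (adjusted p = 0.279, edgeR interaction). The gFLM call ended with scaling by total reads (0.0518), without the filter on low counts (1), without the GFP library of replicate 1 (0.416), 2 (1) or 3 (0.156), without the control library of replicate 3 (0.299) and without both libraries of replicate 2 (0.62), and its adjusted p ran from 1.93e-06 to 1. CBF2 stood at 0.88 ± 0.29 (SD, n = 3) in gFLM. The PIF3 region lies in an intron, at 1.51 ± 0.92 (SD, n = 3) in gFLM and 0.13 ± 0.23 (SD, n = 2) in iFLMbeta, where 1 replicate was at -0.03. At q of 0.01 or less in every replicate 1 gene of this list was left in each construct, with an adjusted p of 0.0878, so the call rests on regions near the threshold. It also ended in iFLMbeta when a ratio above 1 was required in both replicates (1 gene, adjusted p = 0.247). Adjusted over the list alone, edgeR called 1 of 13 tested genes in gFLM and 0 of 12 in iFLMbeta.

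**Figure D3:**
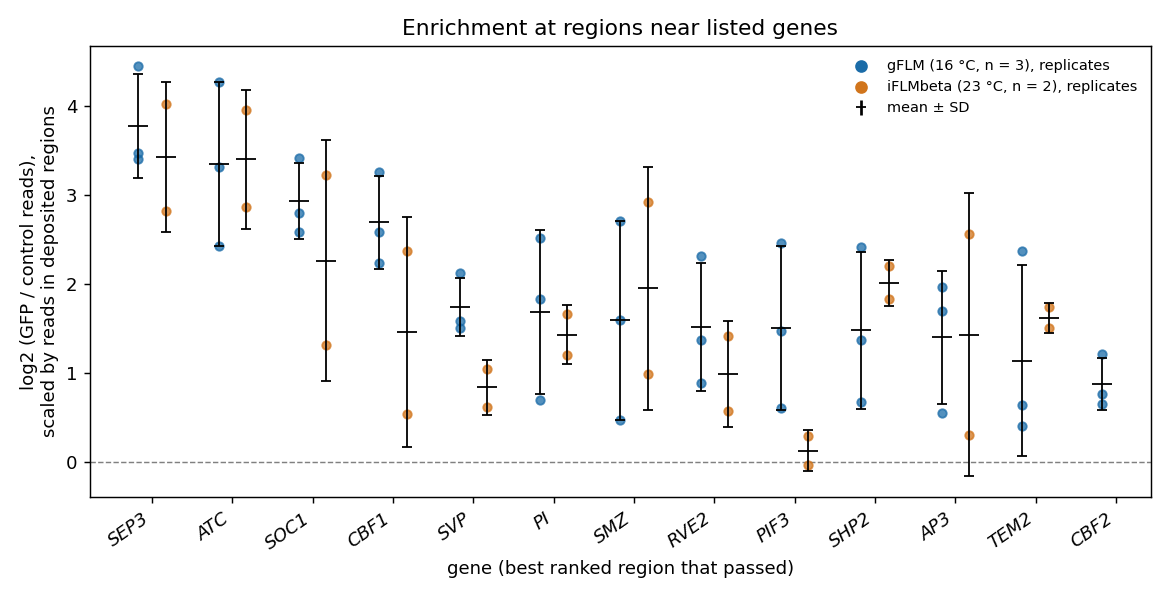
Log2 ratio of GFP to control reads (y axis, scaled by reads in deposited regions) at the best ranked passing region of each listed gene (x axis). Points are replicates of gFLM (blue, n = 3) and iFLMbeta (orange, n = 2), and black bars are mean ± SD. SEP3 is highest in gFLM at 3.77, and the PI region lies outside the assignment window.

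RVE2 was the 1 clock gene of 15 with a passing region, 2599 bp upstream of RVE2 and 2245 bp from AT5G37270 (chromosome 5, 14755470 to 14755906). It stood at 1.52 ± 0.72 (SD, n = 3) in gFLM and 0.99 ± 0.59 (SD, n = 2) in iFLMbeta. The clock list did not pass (adjusted p = 0.229 and 0.254, Fisher's exact test), and edgeR called 0 of 3 and 0 of 6 tested genes over all regions, with 1 and 0 when adjusted over the list alone. With the replicate block RVE2 was called in gFLM (adjusted p = 0.0379), as it was by DESeq2 (0.0203), where edgeR without the block gave 0.439 and the alternatives ran up to 1. Of 13 gibberellin genes and of the 10 highly transcribed control genes, 0 had a passing region in any construct. At most 0.10 was expected for either list in a construct, so 0 does not set them apart from other genes. No gene of any list had a passing region in iFLMdelta, where 0.06 was expected for the flowering list and 0.02 for each other list. So few regions passed in iFLMdelta that 0 was the likely result. There SOC1, SHP2, ATC, PI, RVE2, CBF2 and FT had lower ranked regions with mean log2 ratios between -0.66 (ATC) and 0.38 (RVE2). None of these overlaps the gFLM or iFLMbeta region named for the same gene, so they do not measure iFLMdelta at those sites. For iFLMdelta the tables held no region assigned to SEP3, AP3, SVP, TEM2 or FLM. FT, the mobile flowering signal, had no passing region. Its best gFLM region, in an intron, stood at 0.50 ± 2.46 (SD, n = 3). FLM itself had a single deposited region, in an intron in iFLMbeta, at -0.18 ± 0.66 (SD, n = 2), which did not pass.

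Passing regions of gFLM and iFLMbeta lay mostly outside coding sequence. In iFLMbeta 39.1% of centres were within 1 kb upstream of a gene, against 17.9% of the other deposited regions (adjusted p = 2.18e-11, Fisher's exact test over regions), and 7.4% were in coding exons against 27.7% (adjusted p = 2.18e-11). In gFLM 4.4% were in coding exons against 14.8% (adjusted p = 2.99e-04), while the share within 1 kb upstream, 41.5% against 36.2%, did not differ (adjusted p = 0.301). In iFLMdelta the difference went the other way, with 51.2% in coding exons against 31.3% (adjusted p = 0.036) and 9.8% within 1 kb upstream against 12.8% (adjusted p = 0.854). Those 41 passing regions were fewer than the 84.2 expected from independent replicates, and edgeR called 0 of 4607 tested regions in iFLMdelta. Their positions therefore cannot be taken as those of iFLMdelta binding.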

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

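All tests in this part were chosen after the data had been seen. In 4 regions the enrichment over control differed between constructs in the edgeR interaction, adjusted over regions that passed in either construct. Between gFLM and iFLMbeta this was 1 of 225 regions that passed in either, in the 3' UTR of AT4G35510 (chromosome 4, 16860455 to 16860774). Its log2 enrichment was 3.63 in gFLM and 0.71 in iFLMbeta, a difference of 2.92 with an SE of 0.79 and an adjusted p of 0.047. Of the 225 regions 33 had an unadjusted p under 0.05, and 20 with the median ratio of shared regions set to 1. The median log2 enrichment over the 225 was 1.73 in gFLM and 1.02 in iFLMbeta. On simulated counts the test for this pair recovered 39.0% of regions changed 4-fold, so 1 call does not show equal enrichment elsewhere. Between gFLM and iFLMdelta 3 of 10 differed. At AT5G38600 (chromosome 5, 15460518 to 15460898) the difference was 3.39 (SE 1.05, adjusted p = 0.0134). At AT1G72500 (chromosome 1, 27294329 to 27294669) it was 2.90 (SE 1.08, adjusted p = 0.0322), and at AT1G17940 (chromosome 1, 6174453 to 6174836) it was 2.72 (SE 1.05, adjusted p = 0.0322). All 4 had passed in gFLM and in iFLMbeta, the 3 that differed from iFLMdelta had not passed there, and gFLM plants also differed in age and temperature. Adjusted over all regions deposited for both constructs, 0 of 2331 were called for gFLM and iFLMbeta and 0 of 730 for gFLM and iFLMdelta. With the median ratio of shared regions set to 1, 0 of the 225 and 0 of the 10 regions were called. The AT4G35510 call was kept without gFLM GFP replicate 2 or gFLM control replicate 1 and lost without any other single library. The 3 calls against iFLMdelta became 0 without either iFLMdelta GFP library, 1 without gFLM GFP replicate 2 or the first iFLMdelta control, 2 without gFLM control replicate 3 and 5 without gFLM control replicate 1. Without the second iFLMdelta control 3 regions were called, of which 2 were among these 3. No explanation was tested for these 4.

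The first pattern weighed is the small number of iFLMdelta regions shared by both replicates, with no overlap with iFLMbeta. Chance agreement of the iFLMdelta replicates is left open. The number of regions under the threshold in both replicates was 0.49 times that calculated for independent replicates, where iFLMbeta had 2.05 times. The deposited lists hold many regions with a low q in 1 replicate only, and this selection may lower both numbers. The value of 0.49 therefore cannot separate chance agreement from the effect of that selection. Lower depth stays open. At 733 loci deposited for both, the iFLMdelta GFP libraries held 121.8 and 59.8 reads per kb and the iFLMbeta ones 74.7 and 70.5. The pooled ratio was 1.25, but 0.80 to 1.73 over pairs of libraries (SD 0.50), and passing required a low q in the shallower library too. The control libraries held 53.6 and 43.3 reads per kb there in iFLMdelta and 42.6 and 21.1 in iFLMbeta, so the iFLMdelta controls did not hold fewer reads at these loci. Reads at loci deposited for both are not sequencing depths, so which libraries were shallower cannot be told from them. Weaker occupancy of the iFLMbeta regions also stays open. The odds that a passing iFLMbeta region had a deposited iFLMdelta counterpart were 1.02 times those of other iFLMbeta regions, with a 95% interval of 0.50 to 1.88 that includes a small excess, and whether the protein was present at equal levels was not analysed here.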

How the results depend on the processing

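At the depths and replicate numbers of these libraries, 2-fold changes were rarely recovered from the simulated counts above. The count of passing regions moved with the threshold. At q of 0.01 in every replicate it was 99 in gFLM, 102 in iFLMbeta and 0 in iFLMdelta, and with a ratio of 2 required in every replicate 83, 61 and 16. All deposited regions number 19893, 13791 and 10006. Leaving out 1 replicate gave 173 to 356 in gFLM, 877 to 1551 in iFLMbeta and 557 to 1513 in iFLMdelta, by construction since fewer q-values must pass. The edgeR count in gFLM was 19 scaled by total reads, 97 with DESeq2, 0 without the filter on low counts, 115 with the replicate block, 10 without both libraries of replicate 2 (added after seeing the data), and 6 to 44 with 1 library left out. In iFLMbeta it was 14 without the filter and 14 with the replicate block, and 3 to 23 with 1 library left out. In iFLMdelta all settings gave 0, with the crossed pairing of column numbers too. For the variants the block rests on column numbers that name no library: same-numbered columns correlated at -0.092 and -0.203. The causes were not tested. Pseudocount 5 moved the iFLMdelta replicate correlation to -0.547, and control columns crossed (added after seeing the data) moved it to -0.346 and that of iFLMbeta to -0.335. The gFLM and iFLMbeta overlap was 68 at q of 0.01 and 31 of the best 41 of each, from shorter lists, and other definitions kept it within 1.5 times of 109. The overlaps with iFLMdelta stayed at 0. The median difference of iFLMbeta and iFLMdelta was -0.093 over all regions deposited for both, in place of those passing in iFLMbeta (added after seeing the data). The scaling sets that median near 0, so it does not test the difference. The count of regions differing was 0 to 1 between these with 1 library left out and 0 with the replicate block, 0 to 1 between gFLM and iFLMbeta and 0 to 5 between gFLM and iFLMdelta. With the median ratio or the median count of shared regions set equal, the last 2 pairs gave 0, and with the block 1 and 4. The light and temperature list fell to 1 gene in each construct at q of 0.01 (adjusted p = 0.0878) and in iFLMbeta to 1 with a ratio above 1 in every replicate (adjusted p = 0.247). The other list calls kept their side of the threshold under both other windows, the stricter threshold and a background of genes with any deposited region. In the narrow window the flowering list fell to 2 genes in each construct (adjusted p = 0.0241 in gFLM and 0.0295 in iFLMbeta, Fisher's exact test). The floral organ identity list fell to 2 there (adjusted p = 0.00701 in each). Summits and CArG boxes were not run.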

Other observations

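Beyond the fixed lists, passing regions lay near further genes, named here after their values were seen. ALC and SPT encode bHLH proteins of carpel and fruit development. The region at ALC lies 150 bp upstream (chromosome 5, 26786369 to 26786698), with a log2 ratio of 3.14 ± 1.05 (SD, n = 3) in gFLM and 1.58 ± 0.43 (SD, n = 2) in iFLMbeta. edgeR called it in gFLM (adjusted p = 0.003) and not in iFLMbeta (0.180), and the difference between them was not called (0.279). The region at SPT is 4802 bp away (chromosome 4, 17409178 to 17409472), at 2.18 ± 0.70 (SD, n = 3) and 1.28 ± 0.39 (SD, n = 2), and edgeR called it in neither. A region 728 bp from NAC3 (chromosome 3, 5236643 to 5236990) stood at 2.75 ± 0.51 (SD, n = 3) and 2.41 ± 0.49 (SD, n = 2) and was called in both (adjusted p = 0.012 and 4.17e-05). A region 2167 bp from DMR6, a gene of downy mildew susceptibility, stood at 2.26 ± 1.25 (SD, n = 3) and 1.76 ± 0.27 (SD, n = 2), with an adjusted p by edgeR of 0.131 and 0.034. None of these genes was nearest to a passing iFLMdelta region.

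Of the tests that follow, only the one on gFLM replicate 2 was set before its result was seen. The second pattern weighed is that 50 gFLM and 93 iFLMbeta regions passed in 1 of the 2 constructs. A threshold effect is consistent with the values. Of the 40 gFLM regions that were deposited without passing in iFLMbeta, 87.5% (95% Wilson interval 73.9 to 94.5) lay above the median iFLMbeta ratio, against 53.2% of 2106 shared regions that passed in neither. Of the 76 iFLMbeta regions likewise deposited in gFLM, 98.7% lay above the median gFLM ratio, against 58.8%. The low read number of gFLM replicate 2 alone may account for a part: 30.3% of these 76 passed in replicates 1 and 3. The threshold was missed by 12 in replicate 1, 53 in replicate 2 and 49 in replicate 3.

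A group of 5 iFLMdelta regions over 5768 bp at AT4G14390 and ACD6 (chromosome 4, 8291607 to 8297374), ranked 5 to 24, stood out for being high in 1 GFP library. Their median log2 ratio was -0.85 in replicate 1 and 2.59 in replicate 2. The 5 regions held 116 and 713 GFP reads against 97 and 79 control reads. Neither gFLM nor iFLMbeta had a deposited region there (0 and 0). No explanation was tested.

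The edgeR count of 30 gFLM regions stood against at most 0 in the other splits of the 6 libraries. Of the 10 splits 1, the real one, gave as many regions, and 10 splits are too few for a share under 0.05. This fit leaves the pairing of same-numbered libraries out. The real split parts all 3 pairs, as do 3 of the others, while the other 6 part 1 pair each. With the replicate block the real split gave 116 regions in either direction. The highest count among the other splits that part 3 pairs was 0, and 1 of these 4, the real one, gave as many. These 4 splits are also too few for a share under 0.05. The regions were called on these GFP libraries against these controls, which favours the real split in advance. The low counts of the other splits therefore do not test the grouping, with or without the block.

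Organelle regions were deposited for gFLM only, 14 in all. The 2 chloroplast regions had up to 1305 GFP and 1617 control reads in a library, and none of the 14 passed.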
